A study of Mus musculus with 28 samples.

How the data were processed

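The series holds 28 mouse samples of the C57BL/6 strain, of which 11 peak lists were analysed here: 6 lists of 5-hydroxymethylcytosine (5hmC) and 5 lists of 5-methylcytosine (5mC). All 11 came from bone marrow cells that the labels call LK, of wild-type (WT), Tet2 knockout (Tet2KO) and Tet1 and Tet2 double knockout (DKO) mice. The other 17 samples, RNA-seq libraries in 8 groups, were not analysed here. Per the labels' protocols, 5hmC was captured by selective chemical labelling (hMe-Seal) and 5mC by immunoprecipitation of methylated DNA (MeDIP-seq), and libraries of both assays were prepared with protocols or kits for Illumina sequencing.

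Peaks were supplied by the authors as 1 list per library, without pooling of replicates. The lists have no header, and each peak has a chromosome, a start, an end and the authors' score. The lowest score in any list was 50, and the values have the form in which MACS writes -10 times the log10 of a p-value, so that 50 stands for a probability of 1e-05. Per the submitters' processing notes, CASAVA 1.4, Bowtie 0.12.9, TopHat2 2.0.8, Cuffdiff 2.2.1, MACS 1.4.2 and the build mm9 were used, with no role or order given. Use of a control library, removal of duplicate reads and the read depth of each library are not given in the sources used here. Depth is therefore unknown, and it can change how many peaks a library yields and how wide they are. The deposited score was used to rank peaks within a list and, as alternatives, with a minimum of 100 or 200 for all lists. Such a minimum treats the scores of different libraries as being on 1 scale, which is not known, and 45.5% of 5hmC peaks in WT, 47.3% in Tet2KO and 48.1% in DKO reached 100. Both assays report enrichment, so a peak list shows where signal passed the caller's threshold and not the share of modified cytosines.

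Positions are given in mm9, counted from 1. No gene annotation of that build was used here, so regions and bins are given by position, no genes are named from positions, and the deleted parts of Tet1 and Tet2 were not examined as a check of the labels. The planned tests of gene bodies, promoters and gene lists were not run for the same reason. No peak lay outside the placed chromosomes.

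Groups and replicate numbers came from the titles of the samples. Each group had 2 libraries, except 5mC in Tet2KO, which had 1. Its title gives it the number 2, while the name of its deposited list carries the number 1; the title was followed. The labels do not say that libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. Same-numbered libraries are not said to share an animal or a batch, and the main tests were not blocked.

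Peaks of all libraries of an assay were merged into regions where they overlapped by at least 1 bp. A region was called lost where both libraries of the reference genotype had a peak and both libraries of the other genotype had none, and gained for the opposite. Counts of lost and gained regions were set beside the 2 other ways to split the same 4 libraries into pairs, and beside 100 simulated shuffles of presence that kept the number of regions of each library and the number of libraries of each region. On 5000 simulated regions with 200 planted losses and 200 planted gains, the procedure recovered 200 and 200. These regions lay apart, and no peak was missing or added beyond the planted changes. The result checks the counting only and not the accuracy of calls in real lists. Totals per library were compared by exact two-sided permutation tests: of the slope over WT, Tet2KO and DKO with 90 assignments, for which the smallest p is 0.0222, and of both knockouts against WT with 15 splits, for which it is 0.0667. A comparison of 2 against 2 libraries cannot give a p below 0.333.

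For a genome-wide test, the fraction of each 100 kb bin covered by peaks was transformed by the arcsine of the square root and fitted with limma (trend in the prior variance), with all libraries of the assay in 1 fit, for bins with a peak in at least 2 libraries. Benjamini-Hochberg adjusted p-values under 0.05 counted as calls. Simulated 5hmC data for DKO against WT had 13476 bins, of which 200, drawn from all bins, were changed. On the arcsine scale, limma recovered 1.5% of changes of 0.05 and 70.5% of changes of 0.1 (with 11 false calls). It recovered 100% of changes of 0.2 (with 9 false calls). For a bin at the mean coverage of 7.87%, these changes lead to 10.8%, 14.1% and 21.7% covered. Other bins started from their own coverage, so their changes in percent differed. Simulated bins of equal mean coverage had the same spread, while the spread of real bins varied more. Recovery in the real data can therefore be lower. In DKO against Tet2KO, a real change of 0.197 on the arcsine scale on chromosome 11 was not called (limma, adjusted p = 0.409). The largest simulated change was 0.2 on that scale. The overlap of lost 5hmC with gained 5mC was tested by an exact two-sided permutation that flipped the sign of the difference per chromosome over 20 chromosomes. Intervals on shares of regions are exact Clopper-Pearson 95% intervals, which cover counting error only, as neighbouring regions are not independent.

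By a rule fixed before the data were examined, the bins named are the 5 with the largest fall and the 5 with the largest rise among those past the threshold whose libraries do not overlap between the groups, or, where none passed, the 5 in each direction with the smallest unadjusted p, given as values. The regions named are the widest lost and the widest gained. Alternatives fixed at the same time were a minimum score of 100, an equal number of top peaks per library, autosomes alone, 1 kb bins in place of merged regions (present where peaks covered a fraction of at least 0.5, absent where they covered none), bins of 1 Mb, log2 of the fraction plus 0.01, centring of libraries, no filter or a mean covered fraction of at least 0.05, kept regions matched for width, a replicate block, and leaving out each replicate. The simulated shuffles, the comparison of both knockouts with WT and the test of median peak width were not part of that plan. The share of 5hmC peaks on 5mC regions, a minimum score of 200, the 64235 top peaks of each 5hmC list and the scan for bins in which 1 library lies at least 10 percentage points beyond all others of its assay were added after the data had been seen. Some alternatives could not change a result. The difference of DKO from WT in 5hmC covered length, peak number and share on 5mC regions uses no Tet2KO library. Leaving out a Tet2KO library, or adding the replicate block, leaves this difference unchanged. The 5mC covered length of DKO against WT cannot pass the threshold, as 2 against 2 libraries give no exact permutation p below 0.333.

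Calculations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.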

Results

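Tet1 and Tet2 encode dioxygenases that oxidise 5mC to 5hmC. The study profiled both marks in LK bone marrow cells of young WT, Tet2KO and DKO mice, in a series concerned with B-cell malignancy after combined loss of both genes. The 5hmC libraries, 2 per genotype, had 128471 and 135265 peaks in WT, 137013 and 140491 in Tet2KO, and 130077 and 143960 in DKO. The 5mC libraries had 126995 and 140979 peaks in WT, 138122 in the single Tet2KO library, and 147934 and 120243 in DKO.

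The 5hmC peaks were wider than the 5mC peaks. Median 5hmC width was 704.5 ± 33.2 bp in WT (SD, n = 2), 615.5 ± 24.7 bp in Tet2KO (SD, n = 2) and 664 ± 58.0 bp in DKO (SD, n = 2), against 302 ± 26.9 bp for 5mC in WT (SD, n = 2). Merged over all libraries, the 5hmC peaks gave 206417 regions, of which 61659 (29.9%) had a peak in all 6 libraries, and the 5mC peaks gave 218122 regions, of which 70562 (32.3%) had a peak in all 5. Replicates did not resemble each other equally. Of the 5hmC regions called in either library of a pair, 62.7% were shared by the WT pair and 64.3% by the DKO pair, but 54.2% by the Tet2KO pair, which was below every pair of libraries from different genotypes (55.9% to 61.0%).

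The first question was whether the amount of 5hmC called fell with the number of Tet genes lost. It did not follow that order. In Tet2KO the peaks covered 100.006 ± 2.12 Mb (SD, n = 2), and in DKO, which lacks Tet1 as well, 107.9 ± 2.97 Mb (SD, n = 2), beside 110.4 ± 1.80 Mb in WT (SD, n = 2). The difference from WT was -9.40% for Tet2KO and -2.23% for DKO, and the slope over the 3 genotypes did not pass (exact permutation p = 0.711, adjusted 0.711 over 4 quantities). The slope test asks for an ordered change only and does not weigh the lower value of Tet2KO by itself. In DKO the peak number differed from WT by 3.91% and the median width by -5.75%. The slopes over the 3 genotypes did not pass for either quantity (exact permutation p = 0.444 for each, adjusted 0.593). With peaks of a score of at least 100, the covered length in DKO was 1.80% above WT, and without DKO replicate 2 the peak number was -1.36% from WT, so neither direction was stable.

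**Figure D1:**
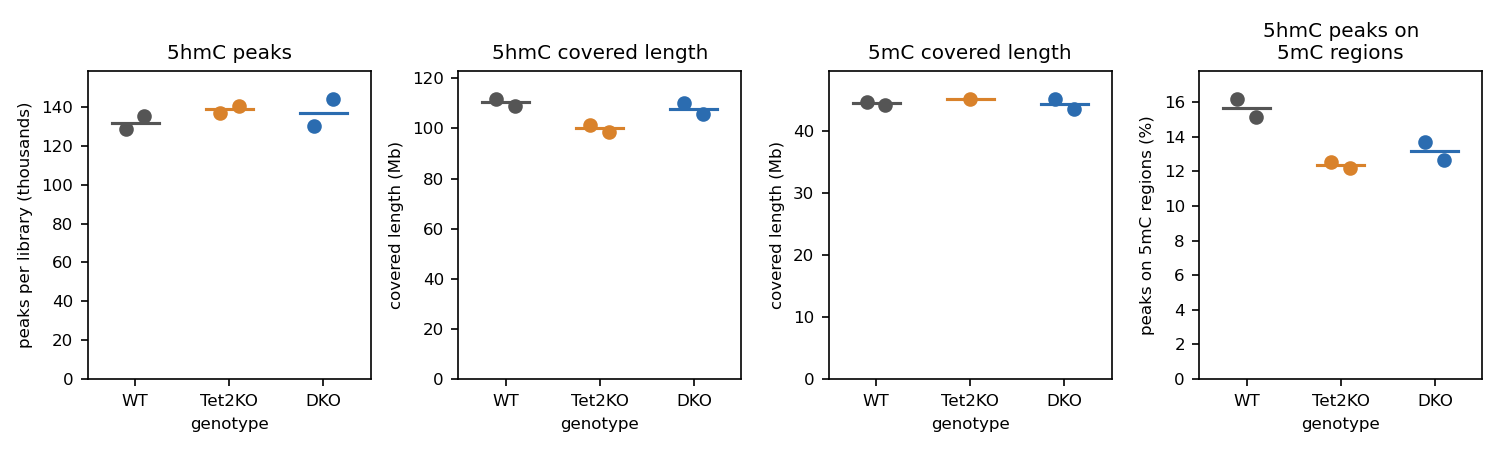
Peak number, covered length in Mb, and percentage of 5hmC peaks on 5mC regions, with 1 point per library and a bar at the mean of each genotype. The covered 5hmC length is lowest in both Tet2KO libraries (101.5 and 98.5 Mb), and all 4 knockout libraries lie below both WT libraries in the share of 5hmC peaks on 5mC regions.

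Loss of Tet2 alone was accompanied by both losses and gains of 5hmC regions. A total of 6744 regions called in both WT libraries were called in neither Tet2KO library, and 7054 regions called in both Tet2KO libraries were called in neither WT library. The widest lost regions lay on chromosome 1 at 158586167 to 158589219 (3053 bp) and 173115328 to 173118288 (2961 bp), where both WT and both DKO libraries had peaks. The widest gained region, on chromosome 15 at 82856540 to 82859556 (3017 bp), had a peak in both Tet2KO and both DKO libraries and in neither WT library. The other splits of the same 4 libraries gave 4441 and 4667 lost and 5459 and 5177 gained regions, and simulated shuffles gave on average 4736 lost (highest 4860) and 5949 gained (highest 6225). With an equal number of top peaks per library the balance turned to 7544 lost and 5728 gained.

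Across 100 kb bins, Tet2KO had lower 5hmC coverage than WT in 7756 bins and higher coverage in 5669 of the 13476 tested, with a mean difference of -0.778 percentage points. The bin with the smallest unadjusted p lay on chromosome 11 at 112900001 to 113000000, with 3.41% and 3.52% covered in the Tet2KO libraries and 13.8% and 13.3% in the WT libraries (limma, adjusted p = 0.197). Other bins with low unadjusted p and less coverage in Tet2KO were on chromosome 4 at 116900001 to 117000000 (13.1% against 22.4%) and 43400001 to 43500000 (20.03% against 32.7%), chromosome 10 at 93100001 to 93200000 (16.7% against 27.6%) and chromosome 15 at 96400001 to 96500000 (21.9% against 33.3%). The bins with the opposite difference were small, the first being chromosome 1 at 186800001 to 186900000 (1.91% against 0 in WT). No bin passed the adjusted threshold in limma, and 1738 bins (12.9%) had an unadjusted p under 0.05, of which 1220 were lower and 518 higher in Tet2KO. When only bins with a mean covered fraction of at least 0.05 were tested, the chromosome 11 bin passed (adjusted p = 0.00196), and with bins of 1 Mb 3 bins passed, all lower in Tet2KO, on chromosome 3 at 153000001 to 154000000, chromosome 10 at 93000001 to 94000000 and chromosome 11 at 113000001 to 114000000.

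Combined loss of Tet1 and Tet2 gave the largest set of gained 5hmC regions among the 3 contrasts. In DKO against WT, 6802 regions were lost and 8621 gained. The widest lost regions were on chromosome 5 at 39178956 to 39181138 (2183 bp) and chromosome 8 at 109592783 to 109594956 (2174 bp). After the chromosome 15 region above, the widest gained regions were on chromosome 8 at 32230744 to 32233282 (2539 bp) and chromosome 2 at 101621616 to 101624065 (2450 bp). Both counts lay above the other splits of the 4 libraries (3153 and 4130 lost, 4983 and 3536 gained) and above the shuffles (mean 4751 lost and 5888 gained, highest 4881 and 6104). The ratio of gained to lost regions was 1.27 for all peaks, 1.73 at a score of at least 100 and 2.63 at a score of at least 200 (1098 lost and 2891 gained), but a minimum score assumes 1 scale for all libraries. With an equal number of top peaks per library, ranked within each list, the counts were 7383 and 7498 (ratio 1.02), and with the 64235 top peaks of each 4277 and 4377 (ratio 1.02). In 1 kb bins the balance turned slightly, with 2916 lost and 2817 gained, but that setting favours the genotype with wider peaks.

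**Figure D2:**
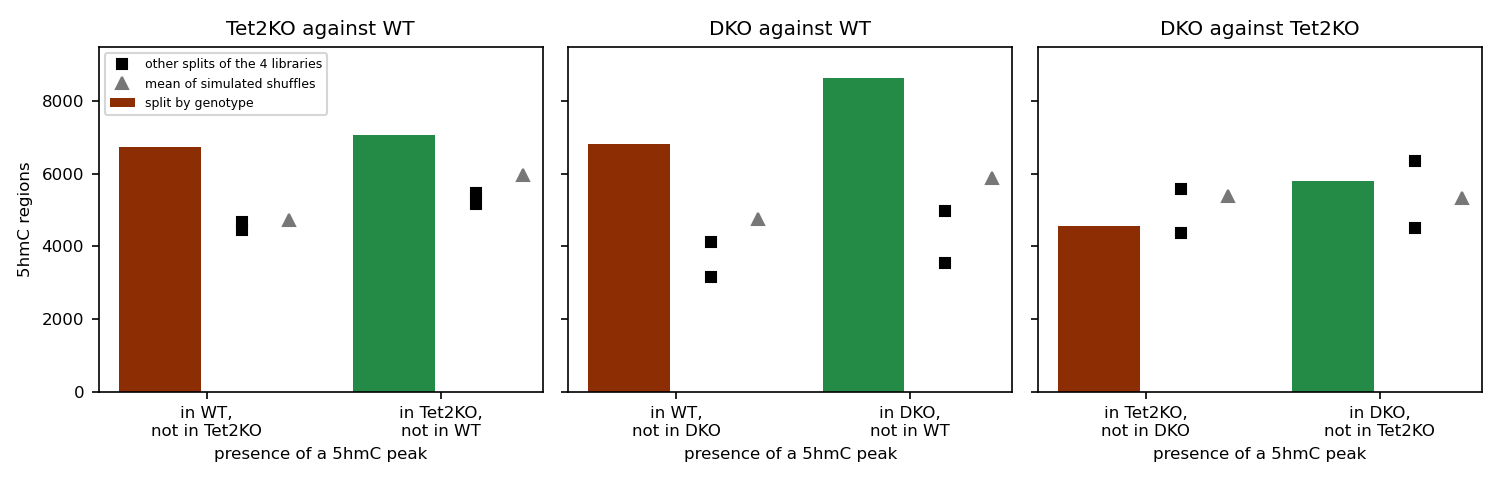
Number of 5hmC regions present in both libraries of 1 genotype and absent from both of another (bars), with the other 2 splits of the same 4 libraries (squares) and the mean of 100 simulated shuffles (triangles). For both knockouts against WT the bars lie above squares and triangles (DKO, 6802 and 8621), and for DKO against Tet2KO they lie between the squares (4569 and 5802).

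Coverage of 100 kb bins did not lean to 1 side between DKO and WT, with 6704 bins lower and 6693 higher in DKO. The mean difference was -0.185 percentage points (SD over bins 1.61). The bin on chromosome 15 at 96400001 to 96500000 had 20.8% and 22.3% covered in DKO and 34.1% and 32.5% in WT (limma, adjusted p = 0.540), and the bin on chromosome 4 at 116900001 to 117000000 had 14.5% in DKO and 22.4% in WT. Both were also among the 5 lowest of Tet2KO. The bin on chromosome 13 at 29300001 to 29400000 had 2.19% covered in DKO, 1.23% in Tet2KO and 0 in WT. No bin passed the adjusted threshold in limma (smallest adjusted p = 0.540), and 1111 bins (8.24%) had an unadjusted p under 0.05, 591 of them higher and 520 lower in DKO.

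The effect of losing Tet1 on top of Tet2 was read from DKO against Tet2KO. Here 4569 regions called in both Tet2KO libraries were absent from both DKO libraries and 5802 showed the opposite, and both counts lay between those of the other splits (4369 and 5589 for the first, 6348 and 4506 for the second). The shuffles gave 5395 (highest 5512) and 5328 (highest 5483), so the second count lay above them, as did 1 of the other splits. The widest regions of the first kind lay near the start of chromosome 9, at 3024272 to 3027919 (3648 bp), where WT replicate 2 had a peak as well, and at 3003852 to 3006072 (2221 bp), where no WT library had one. The bins with the smallest unadjusted p had more 5hmC coverage in DKO. They were the adjacent bins on chromosome 11 from 112900001 to 113100000 (13.0% and 16.6% in DKO, 3.47% and 4.88% in Tet2KO) and a bin on chromosome 9 at 103000001 to 103100000 (17.5% against 7.59%). The WT libraries had 13.8% and 13.3% in the first chromosome 11 bin, 12.1% and 11.2% in the second, and 15.4% and 13.3% in the chromosome 9 bin. No bin passed in limma (smallest adjusted p = 0.260, 1139 bins with an unadjusted p under 0.05), whereas 3 bins, the 3 just named, passed when only bins with a mean covered fraction of at least 0.05 were tested (adjusted p = 0.00179, 0.00179 and 0.0240).

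Regions lost or gained in Tet2KO were often also lost or gained in DKO. Of the lost regions, 2738 were shared, which was 40.6% of the Tet2KO list and 40.3% of the DKO list. Of the gained regions, 2684 were shared, which was 38.0% and 31.1%. Independent lists would share 222 and 295 regions, and shuffles with no effect, in which both contrasts used the same WT libraries, gave 1611 (highest 1695) and 1497 (highest 1626). The shuffled lists were shorter, with on average 4736 (Tet2KO) and 4751 (DKO) lost and 5949 and 5888 gained regions. The shared counts alone therefore overstate the lead over the shuffles. The 2 WT libraries could not be divided between the contrasts with 2 in each, so part of the excess may come from the shared controls.

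For 5mC, DKO and WT differed little in amount. The peaks covered 44.3 ± 1.14 Mb in DKO (SD, n = 2) and 44.4 ± 0.414 Mb in WT (SD, n = 2), a difference of -0.285% (exact permutation p = 1, smallest possible 0.333), and 45.1 Mb in the single Tet2KO library. In DKO 5171 regions were lost and 5521 gained, while the other splits gave 6412 and 3528 lost and 4254 and 9699 gained, so that both counts lay between those of the other splits. The shuffles gave 5452 lost (highest 5608) and 5301 gained (highest 5491), so the gained regions lay above them, as did 1 of the other splits. The widest lost region was on chromosome 8 at 121849048 to 121850015 (968 bp) and the widest gained region on chromosome 11 at 118348343 to 118349308 (966 bp). No 100 kb bin passed among 20403 tested in limma (smallest adjusted p = 0.943), and 941 (4.61%) had an unadjusted p under 0.05. The bin with the smallest unadjusted p, on chromosome 16 at 41300001 to 41400000, had 0.599% covered in WT and 0 in DKO.

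Against WT, the single 5mC Tet2KO library stood apart in 2 adjacent bins on chromosome 2 from 77700001 to 77900000. It had 38.6% and 16.2% of these bins covered, and WT had 2.08% and 0.867% (limma, adjusted p = 0.000879 and 0.0190). With 1 library the test speaks of that library and not of the genotype. It assumes that the lone library varies like the others, and no bin passed without WT replicate 1 (smallest adjusted p = 0.749) or without WT replicate 2 (0.661), in fits with 1 residual degree of freedom. The coverage of the WT libraries was close, at 2.08% in each for the first bin and 0.807% and 0.926% for the second. Of the 5hmC libraries, Tet2KO replicate 2 alone had dense peaks in the same place.

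**Figure D3:**
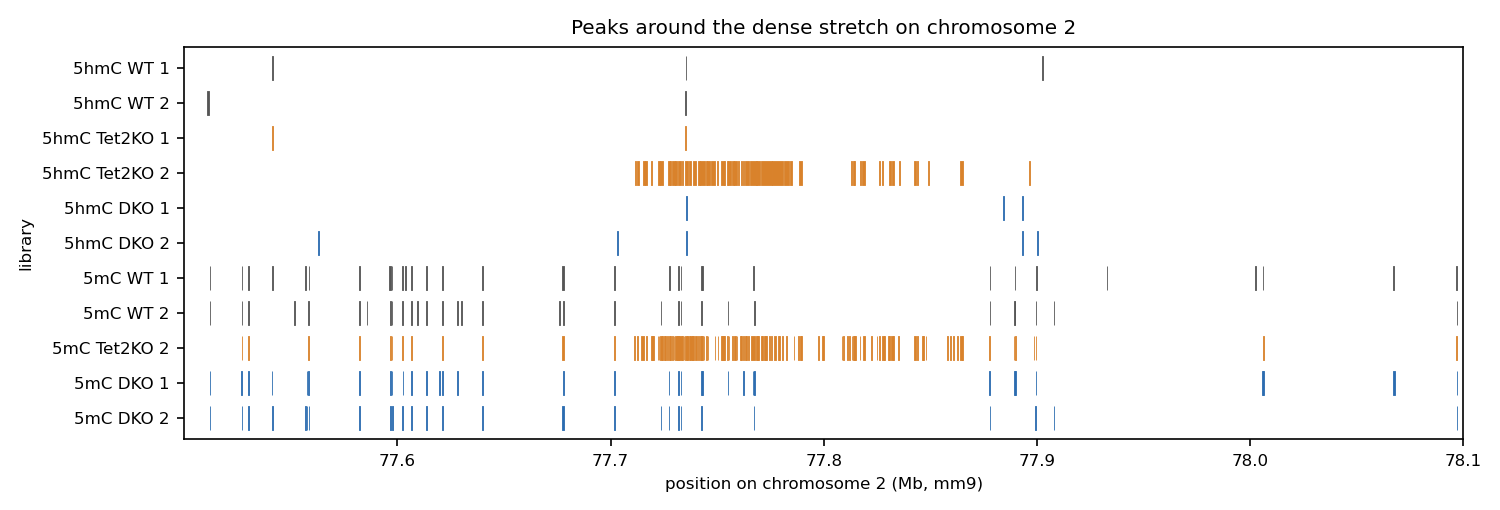
Peaks of the 11 libraries (vertical axis) by position on chromosome 2 in Mb (mm9), each bar being 1 peak. Between 77700001 and 77900000 the 5mC Tet2KO library has 116 peaks and the 5hmC library of Tet2KO replicate 2 has 55, and the other libraries have 1 to 15.

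Because TET enzymes use 5mC as substrate, it was asked whether 5mC appeared where 5hmC was lost in DKO. No excess was found in the overlap of called regions. Of the lost 5hmC regions, 0.985% overlapped a gained 5mC region, and of the regions kept in all 6 libraries, 1.82% did, a difference of -0.838 percentage points in these libraries, lower on 18 of 20 chromosomes (exact sign-flip permutation p = 1.34e-05). Kept regions were wider, with a median of 1182 bp against 710 bp. Against kept regions of matched width the share was 0.970%, and the difference was 0.0147 points (exact permutation p = 0.829). The list of gained 5mC regions (5521) was itself between those of the other splits (4254 and 9699), so it may hold mostly differences between libraries. Overlap with that list cannot decide whether 5mC rose where 5hmC was lost.

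Lost and gained 5hmC regions differed in how often they lay on 5mC, a comparison chosen after the data had been seen. The reference was the 70562 regions with a 5mC peak in all 5 libraries. Of the 5hmC regions lost in Tet2KO, 21.6% (95% interval 20.6 to 22.6) overlapped such a region, and of those gained 3.86% (3.42 to 4.33). For DKO the shares were 18.8% (17.9 to 19.8) and 4.45% (4.03 to 4.91), and for regions changed the same way in both knockouts 23.0% and 3.35%. Regions kept in all 6 libraries were at 19.9% (19.6 to 20.2), but they were wider (median 1182 bp), so their share is not comparable at equal width. The gap between lost and gained regions was 17.7 points in Tet2KO and 14.3 points in DKO, and in the other splits of the same libraries it was 2.28 and 2.73 points, and 3.01 and 1.73 points. Median widths of lost and gained regions were 710 and 667 bp in DKO and 737 and 645 bp in Tet2KO.

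Counted over all peaks of a library, 16.2% and 15.1% of 5hmC peaks lay on these 5mC regions in WT, 12.5% and 12.2% in Tet2KO, and 13.7% and 12.7% in DKO. The 4 knockout libraries were below both WT libraries, in a test that was not planned, a split as extreme as 15 splits allow (exact permutation p = 0.0667, adjusted 0.267 over 4 quantities). The slope over the 3 genotypes did not pass (exact permutation p = 0.178). In DKO against Tet2KO the gap was opposite, with 7.42% of regions absent from DKO and 11.4% of regions absent from Tet2KO on 5mC (-3.94 points, and 1.27 and -0.932 in the other splits).

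**Figure D4:**
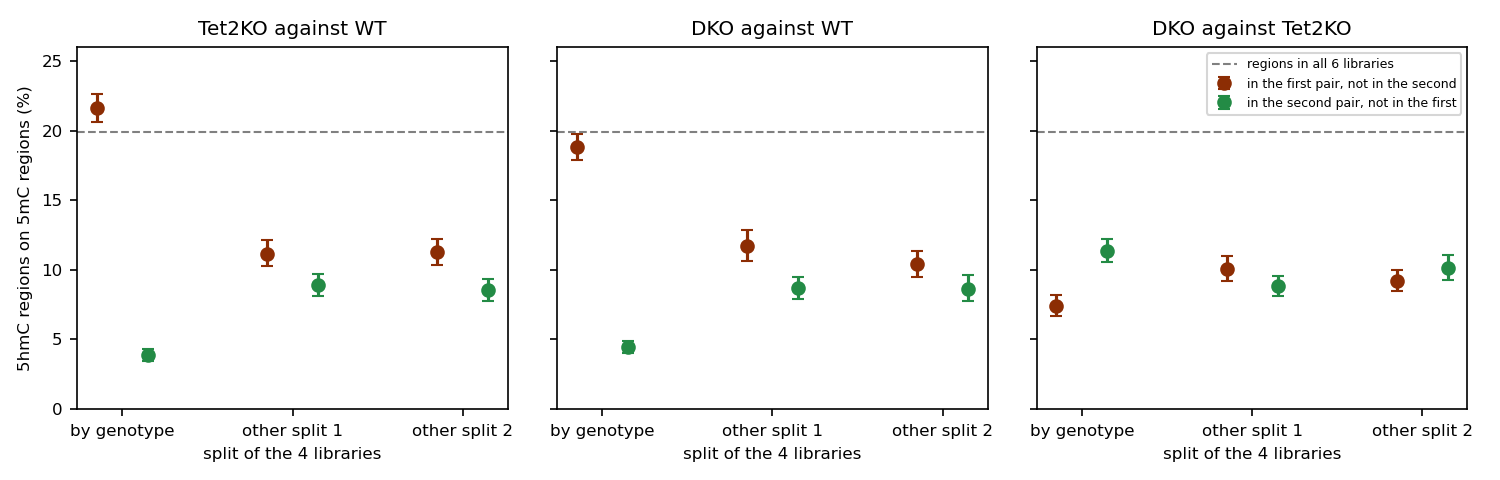
Percentage of 5hmC regions that overlap a 5mC region of all 5 libraries, for regions found in 1 pair of libraries and absent from the other, by split of the 4 libraries, with exact 95% intervals. Split by genotype, regions lost in DKO are at 18.8% and gained regions at 4.45%, while both other splits lie between 8.65% and 11.7%.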

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

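All tests in this part were chosen after the results had been seen.

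The single 5mC Tet2KO library, alone in its group and so not a side of any replicated comparison, though part of the merged 5mC regions, of the reference set and of the limma fit, had signals in places where the WT libraries had little. On chromosome 2 from 77700001 to 77900000 it had 116 peaks, and the WT libraries had 10 and 11. On the Y chromosome it had 14 peaks, and the WT libraries had 3 each.

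The chromosome 2 stretch does not look like a change of 5mC alone, because the 5hmC library of Tet2KO replicate 2 had 55 peaks there, and no other 5hmC library had more than 3. An effect of lost Tet2 is argued against by the same values, since the other 5hmC libraries without Tet2 had at most 3. Extra DNA of this stretch, for example amplified in the cells or carried over in the laboratory, stays open, and other sources were not examined. With peaks at most 10 kb apart joined, the longest 5hmC run of 78.65 kb (77711290 to 77789939) lay 100% inside the 5mC run of 164 kb. That 5mC run fills most of the stretch in which the 5hmC peaks had been seen, so the overlap decides nothing. Past wider gaps, more 5hmC peaks of the same library followed from 77812776 to 77865343, with a last one at 77896371. The 5mC peaks were dense from 77710833, and their run ended at 77865310. The nearness of these ends was seen and not tested. The titles give both libraries the number 2, but the name of the deposited 5mC list carries the number 1, so whether both came from 1 sample is not settled by the labels.

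The X chromosome held 0.567% of the covered 5mC length in the Tet2KO library, 0.454 times the WT mean, with 1.29% and 1.21% in WT, 1.21% in DKO replicate 1 and 0.873% in DKO replicate 2. A lower peak yield of this library is argued against by its 138122 peaks, which lie within the range of the others. More male DNA in this library stays open, since its 14 Y peaks, against at most 4 in the other 5mC libraries, are part of the pattern itself. The labels give no sex, and no 5hmC library had a Y peak. The 5hmC library of Tet2KO replicate 2 had a higher X share (0.341%) than WT (0.265% and 0.260%), as had the other knockout 5hmC libraries (0.303% to 0.383%). This gives no sign of the same pattern in 5hmC. With no Y peaks and few X peaks (445 to 693 per library), the 5hmC lists cannot decide the question.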

How the results depend on the processing

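Alternatives for the share of 5hmC peaks on 5mC regions and for the 5mC Tet2KO bins were chosen after the results had been seen. Among the alternatives for the main results, 91 kept the sign and the side of the threshold, or a count within 1.5 times. Another 51 moved a count further and 6 reversed a sign. Some of the 91 were fixed by construction, as described above. Causes not given were not tested. 5hmC covered length in DKO against WT was -2.23%, 1.80% at a score of at least 100 and -4.50% with an equal number of top peaks (-4.13% to -0.333% without 1 replicate). Without WT replicate 1 its slope over the 3 genotypes turned from -1.23 to 0.619 Mb. Peak number was 3.91%, 9.85% at a score of at least 100, and without 1 replicate -1.36% (without DKO replicate 2) to 9.17%. 5mC covered length was -0.285%, 0.231% with an equal number of top peaks, and -2.10% to 1.53% without 1 replicate (0.376% without WT replicate 1). The difference in 5mC gain at lost 5hmC regions was -0.838 points, 0.0147 with kept regions of matched width, where the wider kept regions had made the gap, and -2.76 to -0.621 without 1 replicate. The share of 5hmC peaks on 5mC regions was lower in DKO by -4.29 to -1.94 points over its alternatives, and at a score of at least 200 it was 30.5% and 29.6% in WT and 23.7% and 21.7% in DKO.

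Region counts were lower with stricter peaks and with 1 kb bins, and grew by over 1.5 times when any 1 of the 4 libraries compared was left out, since fewer libraries then had to meet the criterion. At a score of at least 100, lost and gained 5hmC regions were 3052 and 3943 in Tet2KO, 3196 and 5520 in DKO, and 1993 and 2972 in DKO against Tet2KO, and 5mC regions 2160 and 2131. In 1 kb bins they were 3341 and 1482, 2916 and 2817, and 865 and 2205, and for 5mC 5 and 6. Lost 5hmC bins thus outnumbered gained ones against WT in Tet2KO and, by little, in DKO. Without 1 replicate, the lost 5hmC regions ranged from 15720 to 19983 in Tet2KO, 12828 to 21095 in DKO and 9506 to 22083 in DKO against Tet2KO, and the gained from 13112 to 25219, 16090 to 24867 and 14341 to 20028. For 5mC in DKO they ranged from 9378 to 25056 lost and 11351 to 27641 gained. With an equal number of top peaks all 8 counts stayed within 1.5 times, although in Tet2KO lost regions then outnumbered gained ones (7544 and 5728).

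The limma calls on 5hmC bins were 0 in the 3 contrasts. Without 1 replicate, a lone library was assumed to vary like the others. With a mean covered fraction of at least 0.05 they were 1 for Tet2KO against WT and 3 for DKO against Tet2KO, and in bins of 1 Mb 3 for Tet2KO against WT. For DKO against WT, and for 5mC in DKO, they stayed at 0 under every alternative run and without any 1 replicate. The 2 bins of the 5mC Tet2KO library became 0 at a score of at least 100, with no filter, and without WT replicate 1 or 2, and 35 in bins of 1 Mb, where 4 were higher and 31 lower, all 31 on X. With a mean covered fraction of at least 0.05 they were the first of these and 1 on chromosome 4. By construction, the replicate block left DKO minus WT at -2.23% for 5hmC covered length, 3.91% for peak number and -2.46 points for the share on 5mC regions. Their slopes then had an exact permutation p of 0.722, 0.389 and 0.222, and the 4 replicated bin contrasts 0 calls. Deviations of same-numbered libraries correlated at -0.0142 to 0.0412 for 5hmC and -0.0562 for 5mC across bins. Gene bodies, promoters and gene lists were not run. Depth is unknown, so that a missing peak is not an absent mark.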

Other observations

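In this part the test of neighbouring regions was fixed before its result was seen; the other tests were chosen afterwards.

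Both marks were unevenly spread over the chromosomes. Chromosome 11 had the densest coverage in both assays, with 70.6 kb of 5hmC peaks per Mb (64.5 to 74.5 over 6 libraries) and 26.1 kb of 5mC peaks per Mb (25.8 to 26.6 over 5 libraries), as far as peaks reached along each chromosome. Chromosomes 17 and 19 followed for 5hmC with 60.2 and 58.7 kb per Mb, and chromosomes 5 and 17 for 5mC with 23.9 and 23.8. Among autosomes chromosome 14 was the sparsest for 5hmC (29.6) and chromosome 3 for 5mC (12.2). The X chromosome had 1.99 kb per Mb for 5hmC and 2.75 for 5mC, far below every autosome in both assays.

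The Tet2KO 5hmC libraries were the least alike. Regions found in 1 library alone made up 9.80% and 9.06% of their regions, 5.75% and 7.22% in WT, and 4.30% and 7.32% in DKO. At a score of at least 200 the Tet2KO pair shared 49.1% of regions, the WT pair 61.8% and the DKO pair 63.5%. All 100 kb bins in which 1 library lay at least 10 percentage points beyond every other library of its assay belonged to Tet2KO libraries: 1 higher and 3 lower for 5hmC replicate 1, 3 higher and 5 lower for 5hmC replicate 2, and 2 higher for 5mC.

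The lower share of knockout 5hmC peaks on 5mC regions was weighed further. Weak peaks near the caller's threshold are argued against, because at a score of at least 100 the gap between DKO and WT grew from -2.46 to -4.29 points, and with the 64235 top peaks of each list to -3.64 points. Narrower peaks are argued against as the whole source, because with the centre base of each peak alone the gap was -2.22 points and every knockout library (8.59% to 9.01%) stayed below both WT libraries (10.9% and 11.4%). An accidental split of the 6 libraries cannot be told apart from a genotype effect, since 1 of 15 splits gave a gap as large and no fewer was possible. A genotype effect and a different capture or cell makeup of the WT samples stay open, untested.

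It was also asked whether the change in DKO covers stretches longer than 1 region. Of neighbouring changed 5hmC regions within 10 kb of each other, 57.4% (55.4 to 59.3) changed the same way, beside 53.8% and 50.5% in the other splits of the 4 libraries. The lead over the higher split was under the 5 points set in advance and the intervals overlap, so the question stays undecided. In Tet2KO against WT the share was 56.7%, and the other splits gave 57.5% and 59.7%.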
